A study of Chlamydomonas reinhardtii with 6 samples.

How the data were processed

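Per the labels, total RNA from cultures of 1 algal strain was sequenced on an Illumina GAII instrument, with 3 biological replicates in each of 2 conditions. The deposited values used here are placed reads: each line gives the position, strand, sequence and mismatches of 1 read on a reference sequence, with no count per gene. Per the submitters' processing notes the tools were Bowtie and GSNAP, without versions or settings. The genome build is not given in the sources used here, and positions in 5 of 17 chromosomes ran past the gene table at hand, so that table was not used. Reads were 75 nt and numbered 10883130, 12398833 and 10716533 for N-replete replicates 1 and 2 and N-deprived replicate 1. Other placements were noted for 15, 23 and 14 reads. Whether every other read had a single placement was not checked, which bears on loci of near-identical sequence. The share without a mismatch was 42.6%, 44.5% and 63.2%. The other 3 replicates named in the labels were not analysed here.

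The reference bases under the reads were recovered from the read sequences and their mismatches, giving 59.0 Mb with 0 conflicting positions. Transcribed regions were stretches covered by at least 10 reads over all libraries together, joined over gaps of up to 300 nt, which gave 53363 regions without use of the conditions. Each read was counted by its midpoint, on both strands, since 50.6% to 51.3% of reads in matched loci lay on the strand of the match. The scaffold matching chloroplast proteins and the sequences with ribosomal RNA motifs were left out of the library sizes.

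The rule for named genes, written before the data were examined, took names only from an annotation given with the files. As none of the build in the files was given, loci were instead described by similarity to protein families, a departure chosen after the files were seen. The recovered reference was compared by tblastn (BLAST+ 2.17.0) with 109 protein sequences written from general knowledge, not taken from a database or checked against one. The first round had 88 sequences, with an E value of at most 1e-10, at least 45% identity and 40 residues. After it was seen which of them matched, 21 more were added and the limits loosened to an E value of 1e-06 for a first hit and 0.001 for its extension, 40% identity, and 45% for the best hit over 30 residues or more, with 25% of the sequence covered. Both rounds came before any comparison of libraries by feature, though the share of reads on each reference sequence had been seen. Hits up to 4000 nt apart were joined and loci up to 1500 nt apart merged. This gave 174 loci for 88 of 108 products, 118 of them from first-round sequences at the first limits, with a median identity of 60.0% (43.8% to 99.0%). The loci replaced the regions they lay in, giving 53234 features.

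Of 24 gene lists fixed before the data were examined, 17 had a locus. The 7 without one were aminoacyl-tRNA synthetases, triacylglycerol synthesis and lipid droplets, membrane glycerolipid synthesis, lipases, gametogenesis and mating, sulfur and phosphorus starvation genes, and transcription factors, so they have no result. Other conserved families form a further group that was not among the fixed lists. It was taken out of the family of list tests after a first run had been seen, which moved the histones and cell cycle list from an adjusted p of 0.0496 to 0.0503, across the threshold. The rule for named genes took the 10 largest changes each way among loci past the threshold with at least 10 CPM in the higher condition and the same direction against both N-replete libraries, then up to 2 per list by the smallest p. This named 30 loci, 8 higher and 10 lower by size and 24 by list. A fixed set of gene symbols that was always to be named could not be matched and was left out, and other loci in the text were chosen after their values were seen.

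Because the files hold placed reads and not counts per gene, the fallback fixed beforehand was used: limma-trend on log2 CPM (limma 3.58.1, R 4.3.3). Features needed the CPM that 10 reads give at the median depth in at least 1 library and 15 reads in all. Libraries were scaled by TMM (trims of 0.3 and 0.05, written out in R), and 2 reads were added as a prior count. The threshold was a two-sided Benjamini-Hochberg adjusted p of 0.05 over all 38638 features. Lists with at least 5 loci tested were compared with all other features by camera with a preset correlation of 0.01, adjusted over 12 lists. Beside it stand an estimated correlation and the median against 10000 random lists of like expression. Other splits of the samples were not counted, as the groups held 2 and 1 libraries. Shares carry exact Clopper-Pearson 95% intervals from SciPy 1.17.1, and Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6 handled the tables.

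On simulated data with 200 changed features, of which those tested are given here, the test recovered 40 of 67 at 2-fold, 61 of 67 at 4-fold and 64 of 66 at 8-fold, with 13 false calls among 178. That simulation set its spread from counts with a dispersion of 0.0117, the same for every feature. The real features varied unevenly, with standard errors of 0.23 for phosphoglycerate kinase and 1.69 for nitrate reductase. Its recovery and false calls hold for that even spread and do not describe the real test. Alternatives planned before the data were examined were other scalings, filters, read sets, a fold minimum, each N-replete library alone and other list tests. Voom, removal of a GC trend (lowess span 0.3), other ways to form features, the loci of the first round alone and the calls of single loci over the other read sets were added after the data were seen.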

Results

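Transcripts were measured by RNA sequencing in Chlamydomonas reinhardtii strain dw15.1, a green alga lacking a normal cell wall. Its labelled genotype lists nit2, an allele of a gene that regulates nitrate use, whose effect was not tested here. Cultures grew in acetate medium with 10 mM ammonium (N-replete) or spent 48 h in the same medium lacking nitrogen (N-deprived). The labels give 3 biological replicates per condition, of which 2 N-replete libraries and 1 N-deprived library were used here. Placed reads numbered 10883130 in N-replete replicate 1, 12398833 in N-replete replicate 2 and 10716533 in N-deprived replicate 1. Both N-replete libraries carried a different instrument name from the N-deprived library, so instrument and condition cannot be told apart. Levels are library-scaled reads (CPM), with the N-replete value as mean ± SD (n = 2) and the N-deprived value from 1 library without a replicate. Log2 fold changes are N-deprived over N-replete, each with its standard error (SE) from limma-trend and a Benjamini-Hochberg adjusted p. Genes are named as loci of a protein family, by the similarity of the translated reference to sequences written from general knowledge, so a locus is a family match and not an identified gene. Coordinates are 1-based on a genome build not given in the sources used here.

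Nearly all placed reads lay outside the chloroplast genome and a scaffold with ribosomal RNA. Mitochondrial sequence was not identified, so it was not told apart from nuclear sequence. The chloroplast genome held 0.0958% of reads in N-replete replicate 1 (exact Clopper-Pearson 95% interval 0.0940 to 0.0977), 0.0479% in N-replete replicate 2 (0.0467 to 0.0492) and 0.0452% in the N-deprived library (0.0439 to 0.0465). A scaffold with ribosomal RNA held 0.132% (0.130 to 0.134), 0.0306% (0.0297 to 0.0316) and 0.0581% (0.0567 to 0.0596) in the same order. These intervals cover counting error only. The N-replete libraries differed from each other by more for both compartments than these intervals allow, so no difference between the conditions was read from them.

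The N-replete libraries were closer to each other than either was to the N-deprived library. They differed by 2-fold or more at 2984 of 38638 features (7.72%), while the N-deprived library differed that much from N-replete replicate 1 at 10690 (27.7%) and from replicate 2 at 13232 (34.2%). The N-replete libraries still differed by more than counting error, with a chi-square of 15.1 per degree of freedom over 38537 features. Across features, which are not independent replicates, the Pearson correlation of log2 CPM was 0.963 between the N-replete libraries and 0.853 and 0.810 between each of them and the N-deprived library.

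The comparison of the conditions asked which transcripts changed after 48 h without nitrogen. Loci of the photosynthetic apparatus fell together: every one of the 11 chlorophyll a-b binding loci tested, 7 of 8 loci of the Calvin-Benson cycle and 6 of 8 of the photosystems and electron transport were lower. Isocitrate lyase, an enzyme of the glyoxylate cycle used to grow on acetate, fell from 1713 ± 669 to 17.2 CPM. Nitrate reductase, which turns nitrate into nitrite, rose from 3.44 ± 4.72 to 1158 CPM, and an ammonium transporter locus rose from 0.824 ± 0.878 to 135 CPM. A ferredoxin locus, a match to a small electron carrier, rose from 4.07 ± 4.46 to 1183 CPM while another ferredoxin locus fell. The 24 cytosolic ribosomal protein loci had a median log2 fold change of 0.42, and none passed on its own by limma-trend.

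Of 38638 features tested, 2366 were higher and 2731 lower in the N-deprived library at an adjusted p under 0.05, which is 13.2% of them. The features tested comprised 166 family loci and 38472 other transcribed regions. Among the family loci 9 rose, 52 fell and 105 did not pass by limma-trend, and limma voom called 12 of the 105 higher and 13 lower. With reads collapsed by start and strand all 61 called loci kept their direction with a smaller change, 49 of them by more than 1.5-fold, and 49 kept their call. Collapsing keeps 1 read per start and strand, which caps the count of an abundant locus. The change of such a locus shrinks by construction, so a call lost there does not speak against the change. The test had 1 residual degree of freedom, so it assumed that the lone N-deprived library varied like the N-replete ones. Without the low-count filter limma-trend called 0 features, with 12932 at an unadjusted p under 0.05 and 4539 higher and 3062 lower by limma voom, and with reads free of mismatches it called 497 higher and 773 lower.

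The light-harvesting antenna, whose proteins bind chlorophyll and pass light energy to the photosystems, fell throughout. All 11 loci were lower over all features and all 11 when adjusted over the list alone, with a median log2 fold change of -4.44. Locus 2 fell from 438 ± 99.0 to 5.20 CPM (log2 -6.32, SE 0.28, adjusted p = 0.00278), and locus 1 from 124 ± 10.9 to 2.39 CPM (log2 -5.58, SE 0.24). Locus 10 fell from 516 ± 81.9 to 18.2 CPM and locus 5 from 593 ± 185 to 26.4 CPM. In the N-deprived library loci 6 and 8 each had 1 read, giving N-replete to N-deprived ratios of 363 (95% counting interval 65.0 to 14359) and 208 (37.2 to 8252). Locus 11, the most abundant of them, fell from 3968 ± 637 to 395 CPM. With reads collapsed by start and strand 9 of the 11 passed, loci 4 (log2 -0.30) and 11 (log2 -0.32) not, and the median was -1.75. Collapsing caps the count of a locus as abundant as locus 11, so its lost call does not speak against its fall. With reads free of mismatches loci 4 and 11 stood at -2.53 and -3.47. The camera test of the list gave an adjusted p = 6.74e-13, and adjusted p = 0.434 with an estimated correlation. For every list that estimate rests on 1 residual degree of freedom, too few to decide for or against the list. The preset correlation of 0.01 treats the loci of a list as nearly independent. For every list its p therefore measures spread across loci within these libraries and not between cultures.

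Photosystem and electron transport loci mostly fell: 6 of 8 were lower and 1 higher, against 6 lower and 2 higher when adjusted over the list alone, with a median log2 fold change of -2.82. PsbP and PsbO, subunits of the oxygen-evolving complex, fell from 1629 ± 174 to 79.8 CPM (log2 -4.35, SE 0.27, adjusted p = 0.00315) and from 1962 ± 210 to 181 CPM (log2 -3.43, SE 0.29). Plastocyanin, which carries electrons to photosystem I, fell from 2096 ± 61.6 to 213 CPM (log2 -3.30, SE 0.28). Ferredoxin locus 1 fell from 1278 ± 64.3 to 186 CPM, whereas ferredoxin locus 2 on chromosome 16 (1387837 to 1388715) rose (log2 8.69, SE 1.04, adjusted p = 0.0102). The rise of ferredoxin locus 2 was 10.05 on the log2 scale against N-replete replicate 1 and 7.32 against replicate 2, and 4.16 with reads collapsed by start and strand. That locus had 11375 N-deprived reads on 324 matched nt, more than collapsing can keep, so the cap shrinks its rise. Ferredoxin-NADP reductase stood at 331 and 611 CPM (log2 0.89, adjusted p = 0.0791), and passed by limma voom and when adjusted over the list alone. With collapsed reads 3 of the 6 falls passed, those of plastocyanin (log2 -0.35), PsaD (-0.50) and ferredoxin locus 1 (-0.34) not, and the median was -0.42. Collapsing caps the counts of abundant loci such as plastocyanin and ferredoxin locus 1, so their lost calls do not speak against their falls. With reads free of mismatches plastocyanin stood at -3.52, PsaD at -2.94 and ferredoxin locus 1 at -3.08. The list gave an adjusted p = 0.0014, and adjusted p = 0.434 with an estimated correlation.

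In the Calvin-Benson cycle, which fixes carbon dioxide, 7 of 8 loci fell over all features and 7 when adjusted over the list alone, with a median log2 fold change of -2.94. Phosphoglycerate kinase fell from 371 to 18.6 CPM (log2 -4.30, SE 0.23, adjusted p = 0.00278). The rubisco small subunit locus 2 fell from 708 ± 19.4 to 83.6 CPM (log2 -3.08, SE 0.25), and phosphoribulokinase, which makes the substrate of rubisco, had a log2 fold change of -2.89. Rubisco activase did not pass (log2 -0.45, SE 0.30). It was the only locus of this list from a first-round sequence at the first limits. The 7 falls therefore rest on the sequences or limits of the second round. A glyceraldehyde-3-phosphate dehydrogenase locus, of an enzyme named in this list as fixed, was counted among other conserved families instead. It was not called by limma-trend but was higher by limma voom (log2 1.13). All 5 loci of chlorophyll and tetrapyrrole synthesis fell, also when adjusted over the list alone, with a median of -1.80. They comprised 3 magnesium-chelatase subunit ChlI loci, of which locus 2 fell from 34.4 ± 2.56 to 8.63 CPM and locus 1 from 49.1 ± 2.31 to 13.9 CPM, plus glutamate-1-semialdehyde aminotransferase and porphobilinogen synthase. With collapsed reads the medians were -1.13 and -0.98 and 5 Calvin-Benson loci passed, with rubisco small subunit locus 2 (log2 -0.77) and transketolase (-0.39) not. Rubisco small subunit locus 2 had 6819 and 7987 N-replete reads on 285 matched nt, more than collapsing can keep. Its lost call therefore does not speak against its fall. With reads free of mismatches 5 Calvin-Benson and 3 chlorophyll loci passed, with log2 fold changes of -1.34 for fructose-bisphosphate aldolase locus 1, -1.61 for transketolase, -1.58 for ChlI locus 2 and -1.31 for porphobilinogen synthase, which did not pass. The list medians over those reads were -3.06 and -1.58. The adjusted p was 5.81e-07 for the Calvin-Benson list and 0.000184 for the chlorophyll list, and for both adjusted p = 0.434 with an estimated correlation.

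**Figure D1:**
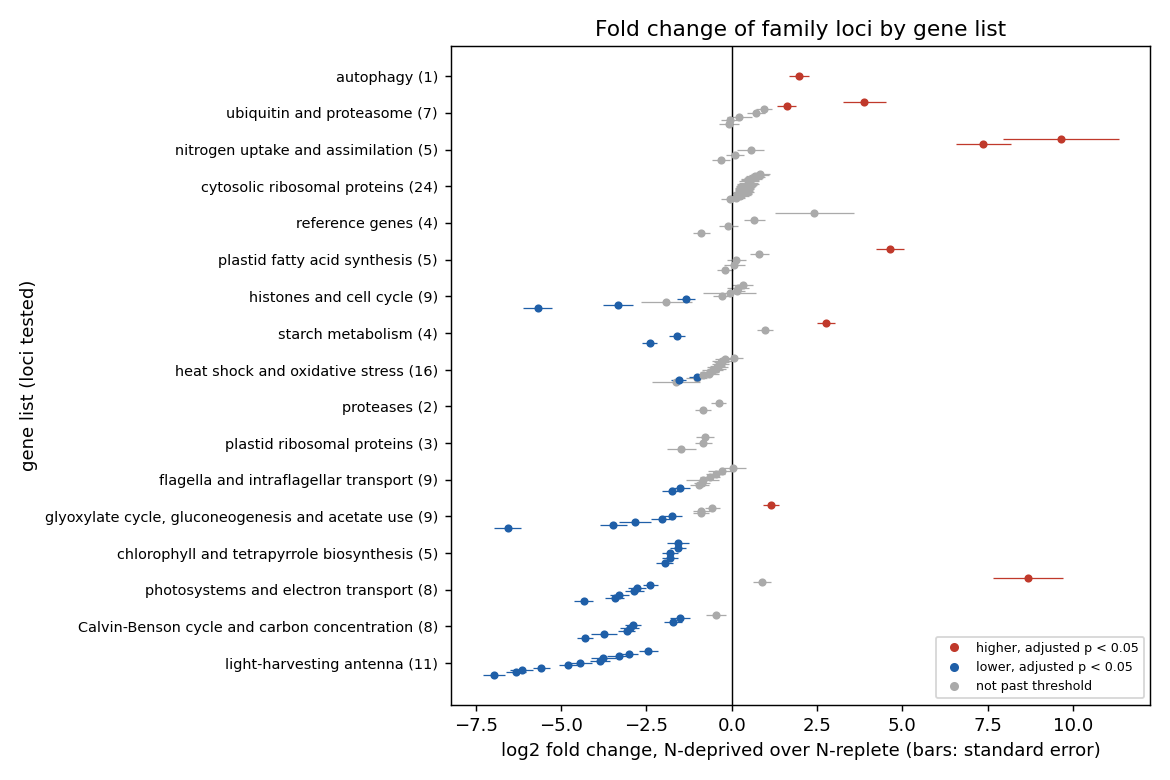
Log2 fold change of each family locus tested (N-deprived over N-replete; points, with bars for the standard error), by gene list with the number of loci in brackets. The 11 light-harvesting antenna loci lie furthest left as a list, with a median of -4.44, and the 24 cytosolic ribosomal protein loci lie close to 0 with a median of 0.42.

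Among loci of the glyoxylate cycle, gluconeogenesis and acetate use, 5 of 9 fell and 1 rose, against 7 and 1 when adjusted over the list alone (malate dehydrogenase loci 1 and 2 in addition), with a median log2 fold change of -1.74. Isocitrate lyase on chromosome 6 (3950338 to 3953603) had a log2 fold change of -6.57 (SE 0.39, adjusted p = 0.00294), which was -6.16 against N-replete replicate 1 and -6.98 against replicate 2. Acetyl-CoA synthetase, which activates acetate, fell at locus 2 from 792 ± 310 to 68.4 CPM (log2 -3.47, SE 0.39) but rose at locus 3 from 21.8 ± 1.57 to 48.8 CPM (log2 1.16, SE 0.24, adjusted p = 0.036). Phosphoenolpyruvate carboxykinase, an enzyme of gluconeogenesis, fell from 775 ± 393 to 101 CPM, and citrate synthase did not pass at 50.4 and 34.0 CPM. With reads free of mismatches 3 fell and 0 rose by limma-trend, as malate dehydrogenase locus 3 (log2 -1.87), phosphoenolpyruvate carboxykinase (-3.03) and acetyl-CoA synthetase locus 3 (1.17) did not pass, at adjusted p = 0.0581, 0.0583 and 0.0852. With collapsed reads the median was -0.78 and isocitrate lyase stood at -3.33. The list gave an adjusted p = 0.00034, and adjusted p = 0.434 with an estimated correlation.

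Of 5 loci of nitrogen uptake and assimilation, 2 rose and 3 did not pass, with the same counts when adjusted over the list alone and a median log2 fold change of 0.56. That median was 3.74 over the 4 loci with at least 50 reads averaged over the 3 libraries (the filter of 50 reads), 0.33 over 6 loci without the low-count filter and 1.14 with reads free of mismatches. Nitrate reductase on chromosome 9 (3789362 to 3792996) rose by 9.65 on the log2 scale (SE 1.69, adjusted p = 0.025). Its adjusted p was 0.054 with collapsed reads (log2 6.46) and 0.0542 with reads free of mismatches (log2 9.47), so its call ended in both. It had 11137 N-deprived reads on 1101 matched nt, more than collapsing can keep. The smaller change with collapsed reads follows from that cap at least in part. It had 1 read in N-replete replicate 1, a ratio of N-deprived to that library of 11380 (95% counting interval 2042 to 449526), and rose by 7.38 on the log2 scale against replicate 2. Ammonium transporter locus 1 on chromosome 13 (1171012 to 1172165) rose by 7.38 (SE 0.81, adjusted p = 0.00859) and passed with either read set. It had 2 reads in N-replete replicate 1, a ratio of 662 (183 to 5473), and rose by 6.36 against replicate 2. Both loci, like ferredoxin locus 2, had higher levels in N-replete replicate 2 than in replicate 1. For nitrate reductase these were 6.77 and 0.102 CPM. How the nit2 allele in the labelled genotype bears on the nitrate reductase rise was not tested. Both loci of glutamine synthetase, which joins ammonium to glutamate, did not pass, at 291 and 234 CPM for locus 2 and 16.1 and 17.2 CPM for locus 1. The list as a group did not pass, with an adjusted p = 0.0748.

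Nitrate reductase lay in a stretch of strongly raised features on chromosome 9. Within 30000 nt on either side, 6 features spanning 24.75 kb (3768247 to 3792996) had a log2 fold change of 5 or more, and all 6 passed. Among them, the region at 3790160 to 3790390 lay within the span of the nitrate reductase match. The next region (3796642 to 3803512) rose from 36.3 ± 1.88 to 1095 CPM (log2 4.91), so the end of the stretch follows from the limit of 5. The stretch took 0.00181% of reads in features in N-replete replicate 1, 0.0156% in replicate 2 and 2.85% in the N-deprived library. Of the unnamed regions that passed with at least 10 CPM in the higher condition, the largest rises were in it: the region at 3780614 to 3787098 rose from 45.2 ± 61.8 to 16838 CPM, and the region at 3775567 to 3779129 from 7.06 ± 9.56 to 2844 CPM. Against N-replete replicates 1 and 2 alone the log2 fold change of the former was 13.25 and 7.56. The latter had 3 reads in replicate 1, a ratio of 9316 (3187 to 45175), and a log2 fold change of 7.66 against replicate 2. The largest falls of unnamed regions were on chromosome 2 (8881876 to 8883396), from 3741 ± 422 to 23.8 CPM, and on chromosome 4 (2534737 to 2536570), from 62.6 ± 31.1 CPM to 2 reads in the N-deprived library, an N-replete to N-deprived ratio of 307 (84.9 to 2539).

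**Figure D2:**
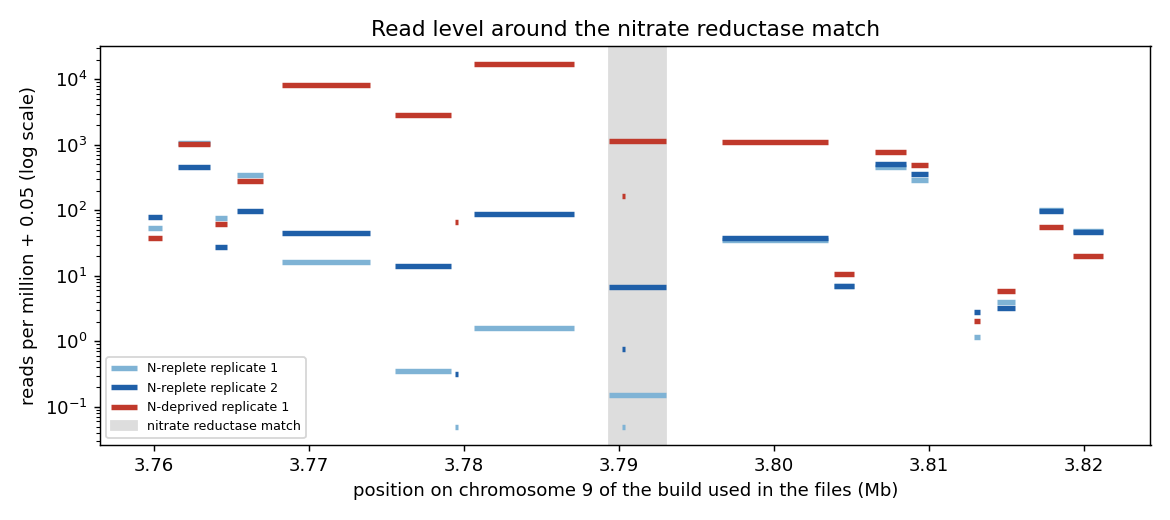
Level in CPM (log scale) of each feature around the nitrate reductase match, by position on chromosome 9 in Mb, for the 2 N-replete libraries and the N-deprived library, with 1 horizontal bar per feature and library and the match shaded. The 6 features between 3768247 and 3792996 are those with a log2 fold change of 5 or more.

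Starch loci went both ways. In starch metabolism (4 loci, too few for a list test) glucan phosphorylase locus 2, a match to enzymes that act on glucan chains, rose from 101 ± 14.8 to 684 CPM (log2 2.76, SE 0.26, adjusted p = 0.00623). ADP-glucose pyrophosphorylase, which makes the precursor of starch, fell at locus 1 from 141 ± 10.3 to 26.3 CPM (log2 -2.41, SE 0.23) and at locus 2 from 281 ± 17.4 to 92.5 CPM. These 3 calls became 2 higher and 2 lower when adjusted over the list alone, with glucan phosphorylase locus 1 in addition. With collapsed reads all 3 passed, at log2 fold changes of 0.90 for glucan phosphorylase locus 2 and -1.49 and -0.83 for the ADP-glucose pyrophosphorylase loci. Glucan phosphorylase locus 2 had 6576 N-deprived reads on 594 matched nt, more than collapsing can keep, so the cap shrinks its rise. Of 5 plastid fatty acid synthesis loci 1 rose, also when adjusted over the list alone: biotin carboxylase locus 3, from 0.474 ± 0.0954 to 16.4 CPM (log2 4.64, SE 0.41). Biotin carboxylases also serve enzymes outside fatty acid synthesis. That list had a median log2 fold change of 0.14, or 0.59 with reads free of mismatches, and an adjusted p = 0.128. Biotin carboxylase locus 2 was also higher by limma voom.

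ATG8, a protein of the autophagosome membrane and the only autophagy locus, rose from 11.6 ± 2.40 to 45.5 CPM (log2 1.97, SE 0.28, adjusted p = 0.0161), but did not pass with reads free of mismatches (log2 1.56, adjusted p = 0.091). With collapsed reads it passed at a log2 fold change of 1.15 (adjusted p = 0.0447). Of 7 ubiquitin and proteasome loci 2 rose over all features and 3 when adjusted over the list alone (ubiquitin locus 5 in addition), with a median log2 fold change of 0.71. Ubiquitin-conjugating enzyme E2 locus 3 rose from 4.96 ± 0.394 to 15.5 CPM, and ubiquitin locus 2 had 0 reads in both N-replete libraries and 26 in the N-deprived library, at least 8.86-fold higher against a floor of 3 reads per library. With that locus at its bound the median stayed at 0.71. With reads free of mismatches 0 of 6 passed by limma-trend, with a median of 0.28: ubiquitin locus 2 had too few reads to test and E2 locus 3 had an adjusted p = 0.0703 (log2 1.60). The list gave an adjusted p = 0.029, and adjusted p = 0.434 with an estimated correlation. Set against random lists of like expression, it did not pass.

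Of 24 cytosolic ribosomal protein loci, parts of the ribosome outside the organelles, none passed with limma-trend, over all features or when adjusted over the list alone. At an unadjusted p under 0.05 there were 3, and limma voom called S3 and S6 higher. Ribosomal protein S3 stood at 871 ± 35.8 and 1558 CPM (log2 0.84, SE 0.28) and S11 at 618 and 596 CPM. As a group they were higher than other features by camera (adjusted p = 0.00219), and adjusted p = 0.599 with an estimated correlation. The 3 plastid ribosomal protein loci had a median log2 fold change of -0.83, with 0 passing over all features by limma-trend, 3 at an unadjusted p under 0.05, 2 lower by limma voom (bacterial-type L13 and L1 locus 2) and 3 lower when adjusted over the list alone. Their median was -0.30 with collapsed reads.

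Cell division and cytoskeleton loci were in part lower. In the histones and cell cycle list 3 of 9 fell, also when adjusted over the list alone, with a median log2 fold change of -0.28 and an adjusted p = 0.0503. That list did pass with the first-round loci alone, and with other conserved families kept among the list tests. Its median was -0.81 over the 6 loci left by the filter of 50 reads, -0.54 over 12 loci without the low-count filter, -0.13 with collapsed reads and -0.41 with reads free of mismatches. Proliferating cell nuclear antigen, the clamp of DNA polymerase, fell from 82.0 ± 39.0 to 7.49 CPM (log2 -3.33, SE 0.44, adjusted p = 0.0123). The other 2 were cyclin-dependent kinase loci, matches to regulators of the cell cycle. Locus 2 fell from 18.5 to 7.18 CPM, and locus 5 fell from 27.3 ± 11.5 CPM to 3 reads, an N-replete to N-deprived ratio of 89.0 (30.3 to 433). In the flagella list 2 of 9 fell, with a median of -0.86: centrin locus 1, from 53.0 ± 11.6 to 15.3 CPM, and beta-tubulin locus 2, from 82.7 ± 20.5 to 28.1 CPM. Alpha-tubulin loci 1 and 2 brought this to 4 when adjusted over the list alone. Centrin and tubulin also serve basal bodies and the cell body. With collapsed reads beta-tubulin locus 2 did not pass (log2 -0.85, adjusted p = 0.0587) and the flagella median was -0.24, and with reads free of mismatches cyclin-dependent kinase locus 2 did not pass (log2 -1.40, adjusted p = 0.0701). The flagella list gave an adjusted p = 0.0064, and adjusted p = 0.434 with an estimated correlation. Against random lists of like expression it did not pass.

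In the heat shock and oxidative stress list 2 of 16 loci fell, also when adjusted over the list alone, with a median log2 fold change of -0.50. Chaperonin 60 locus 2, a match to proteins that help others fold, fell from 50.4 ± 2.18 to 16.9 CPM (log2 -1.56, SE 0.23, adjusted p = 0.0168), and heat shock protein 90 locus 2 from 155 ± 4.13 to 76.5 CPM (log2 -1.02, SE 0.23). With reads free of mismatches neither passed by limma-trend, at log2 fold changes of -1.28 and -1.19 and adjusted p = 0.0615 and 0.0561. With collapsed reads the second did not (log2 -0.57, adjusted p = 0.0656) and the median was -0.21. The 36 loci of other conserved families, which are not a fixed list, had a lower median of -0.59. The heat shock list gave an adjusted p = 0.00219, and adjusted p = 0.434 with an estimated correlation. It did not pass against random lists of like expression.

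No list median changed sign between TMM, median-of-ratios and total-count scaling. These scalings shift all loci nearly alike and by less than the smallest list median, so no sign could have changed.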

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

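The alternatives limma voom, GC trend removal, other ways to form features, the first-round loci and the read sets for replicate agreement were chosen after seeing the data. Of 28 alternative counts 18 stayed within 1.5 times the first value; those that did not follow. Without the low-count filter limma-trend called 0 higher and 0 lower of 52327 features (smallest adjusted p 0.0903; 12932 at an unadjusted p under 0.05; voom 4539 higher and 3062 lower), and its prior degrees of freedom were 2.35 in place of 4.52; the cause was not tested. Reads free of mismatches gave 497 higher and 773 lower of 26114 features, and 1265 of these 1270 calls were shared with the same direction. Voom gave 4620 higher. Regions without joining gave 4786 higher and 6002 lower of 82379 features, 1-kb windows 4551 and 5668 of 73254, and joining over 500 nt 1784 lower of 22616, from the change in the number of features at least in part. Collapsing reads by start and strand moved the antenna median from -4.44 to -1.75, photosystems from -2.82 to -0.42, Calvin-Benson from -2.94 to -1.13, chlorophyll from -1.80 to -0.98, glyoxylate from -1.74 to -0.78, flagella from -0.86 to -0.24, heat shock from -0.50 to -0.21, plastid ribosomal proteins from -0.83 to -0.30, histones and cell cycle from -0.28 to -0.13, ubiquitin from 0.71 to 0.27 and cytosolic ribosomal proteins from 0.42 to 0.13. Collapsing keeps 1 read per start and strand, so the length of a locus caps its count. PsbO, with 867 matched nt, had 20744 and 20077 reads in the N-replete libraries and 1739 in the N-deprived library. At such abundant loci the smaller change follows from the cap at least in part. Whether duplicate reads add to it was not tested. Features 2-fold or more apart numbered 11491, and 10690 to 13232 without 1 N-replete replicate. With an estimated correlation the adjusted p was 0.599 for cytosolic ribosomal proteins and 0.434 for the light-harvesting antenna, Calvin-Benson, photosystem, chlorophyll, glyoxylate, flagella, heat shock and ubiquitin lists, so none of the 9 list calls was kept. With 1 residual degree of freedom that estimate is poor and cannot decide for or against a list. The preset correlation and the random lists compare loci with other features of the same libraries. Their p-values therefore do not measure variation between cultures. Against random lists the adjusted p was 0.0566 for flagella, 0.27 for heat shock and 0.131 for ubiquitin, while the antenna and Calvin-Benson lists reached 0.0012, from an unadjusted p of 0.0002, the smallest the draws can give. Histones and cell cycle gave 0.0176 with the first-round loci. The Calvin-Benson, chlorophyll, glyoxylate, plastid fatty acid and ubiquitin lists had fewer than 5 such loci and could not be retested that way. Of 120 alternative fold changes of the 30 named loci, only those against 1 N-replete library were compared with the SE, and 14 were off by more. That SE rests on the same N-replete libraries. For loci named by size the rule itself required 1 direction against both libraries. With the other scalings every named locus kept its direction and call. No paired analysis was possible because only replicate 1 has both conditions, and a replicate block leaves no residual degrees of freedom. Planned but not run were count models per gene, list members by symbol, reads with several placements, strand-specific counts and shares over all placed reads. The placed reads carry no gene, no symbol, no strand of origin and few notes of other placements. Depth limits loci with 1 to 3 reads in a condition, whose ratios carry wide counting intervals.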

Other observations

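The tests of instrument and of carry-over were chosen after the values they measure were seen. The predictions for mismatches and GC content were written beforehand, though removal of the GC trend as an alternative was added after the data were seen. Outside the fixed lists, 36 loci of other conserved families held 9 that fell and 0 that rose by limma-trend, or 14 and 4 when adjusted over that group alone, with a median log2 fold change of -0.59. With collapsed reads 7 fell and the median was -0.31, as cyclophilin locus 1 (log2 -0.54, adjusted p = 0.104) and eukaryotic initiation factor 4A locus 1 (log2 -0.76, adjusted p = 0.0608) did not pass. With reads free of mismatches cyclophilin locus 9 did not (log2 -1.81, adjusted p = 0.0624), and limma voom called 4 higher and 12 lower. Tested by camera along with the fixed lists, this group was also lower than other features (adjusted p = 0.00127, and adjusted p = 0.476 with an estimated correlation). S-adenosylmethionine synthetase, which makes the cell's main methyl donor, fell from 1912 ± 357 to 172 CPM (log2 -3.46, SE 0.31, adjusted p = 0.00567), with a log2 fold change of -0.96 with collapsed reads. Serine hydroxymethyltransferase locus 2, of one-carbon metabolism, fell from 99.2 to 15.8 CPM, while loci 1 and 3 did not pass by limma-trend (locus 1 was lower by limma voom), at 58.7 and 32.3 CPM and at 42.4 and 68.4 CPM. Of 12 cyclophilin loci, matches to prolyl isomerases, 5 fell, among them locus 10 from 8.58 to 0.832 CPM and locus 6 from 80.0 to 14.5 CPM. These loci were picked after their values were seen.

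Of 4 loci of the reference gene list none passed with limma-trend, over all features or over the list alone, with 1 at an unadjusted p under 0.05 and, by limma voom, actin locus 3 higher and actin locus 1 lower. The largest value was that of actin locus 3, at 14.5 and 48.2 CPM (log2 2.43, SE 1.17). Actin locus 1 stood at 483 and 259 CPM (log2 -0.90), actin locus 2 at 7.64 and 7.07 CPM and RACK1 at 1700 and 2697 CPM (log2 0.67). Actin locus 1 passed as lower with the GC trend removed and with the filter of 50 reads. The 2 protease loci did not pass over all features by limma-trend, at log2 fold changes of -0.84 for the papain-type cysteine protease and -0.39 for a Clp protease subunit. The former was lower by limma voom and when adjusted over the list alone.

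The calls between the N-deprived and the N-replete libraries were weighed against 3 technical explanations. Of 5097 called features, 4539 could be tested over reads free of mismatches. The rest had too few such reads, so errors were not weighed there. The log2 fold changes of the 4539 had a slope of 0.913 on those over every read, with the same direction in 99.96%. Reads free of mismatches are a part of every read, so some of this agreement is built in. For the 4539 features the slope argues against sequencing errors as the whole cause. With the GC trend of each library removed, 99.6% of the called features kept direction and call, which argues against GC bias as the whole cause. The conditions shared 0 instruments, so a batch effect of instrument or run could account for any part of the calls and cannot be told apart from nitrogen supply. The biological explanation, 48 h without nitrogen, stays open with it.

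For 32 features with at least 20 CPM in the N-deprived library and a mean of at most 0.5 CPM over both N-replete libraries, a choice that treats these alike, the level was 0.619% of the N-deprived level in replicate 2 and 0.269% in replicate 1, and higher in replicate 2 for 25 and in replicate 1 for 6. Chosen instead by at most 0.5 CPM in replicate 2, which favours replicate 1, 36 features gave 0.699% in replicate 2 and 1.18% in replicate 1, with 21 higher in replicate 2 and 14 in replicate 1. Carry-over of N-deprived reads at 1 fixed proportion may account for it, in which case the share would be the same for every feature. Over 38 features chosen by at most 0.5 CPM in replicate 1, the chi-square per degree of freedom of the share in replicate 2 was 2.04, with 4 of 1000 simulations at 1 fixed share as high (median 0.996, highest 2.19), which lies between the bounds set for and against carry-over, so the values do not decide. The 6 features of the chromosome 9 stretch had log2 fold changes of 7.16 to 7.66 against replicate 2, and of 8.40 to 13.25 against replicate 1. Against replicate 2, ferredoxin locus 2 stood at 7.32 and ammonium transporter locus 1 at 6.36. A nearly even share in the stretch goes with carry-over, but these features were picked after their values were seen and do not decide either. If reads were carried over, the N-replete means of these loci include them. A lower nitrogen supply in the replicate 2 culture is a biological alternative that was not tested.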
